A study of Rhodococcus jostii RHA1 with 6 samples.

How the data were processed

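Gene expression was measured on 1-colour (Cy3) Agilent arrays in 6 cultures of Rhodococcus jostii RHA1, a soil actinobacterium. Of these cultures, 3 were the wild-type strain and 3 were a transconjugant that had received the plasmid pGKT2 by conjugation. Per the labels' protocols, cultures grew in LB, a rich broth, at 30 °C with shaking at 180 rpm for about 48 h. Total RNA was then prepared with lysozyme, bead beating and an on-column DNase step, and was labelled as cRNA. The labels describe the replicates as separate cultures.

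Each array held 15744 spots. Of these, 15208 carried 9233 gene probes for 9131 locus tags, of which 8972 belonged to RHA1 and 159 to pGKT2. There were 9080 tags with 1 probe and 51 with 3 probes. The scanner files are deposited spot intensity values from Agilent Feature Extraction 10.7.3.1 (protocol GE1_107_Sep09), per the file headers. The software's processed intensity, already background-subtracted per the file headers, was the main input. The authors' deposited value table holds log2 values with 1 row per tag. Its scale is stated in no source used here and was found by comparing each column with log2 of the same array's processed intensity (r from 0.973 to 0.997). Its columns have nearly the same distribution (medians from 5.588 to 5.618), as quantile normalization gives, but the method is not given in the sources used here. The direction of single values is that of signal; no centring of genes was seen.

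Spots flagged as outliers by the scanner software (9 to 17 gene spots per array) and all control spots were left out. No gene spot was saturated. Signals were put on the log2 scale after division by each array's 75th percentile over all gene spots, those of pGKT2 included. Spots of a probe and then probes of a gene were averaged. A gene was tested if at least 1 of its probes was well above background on all 3 arrays of at least 1 strain; a probe counted on an array if at least 50% of its spots were. This left 8822 RHA1 genes and all 159 pGKT2 genes. Strains were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 in 1 fit over all 6 arrays, with Benjamini-Hochberg adjustment separately over RHA1 and pGKT2 genes and a threshold of 0.05. A plasmid gene not well above background on any wild-type array is given as "at least N-fold". That bound is the transconjugant mean over the mean, across wild-type arrays, of the higher of the lowest signal among well-above-background probes and the gene's own signal.

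The files name genes by locus tag alone and no annotation was used here, so tags carry no gene names, positions or products, and no more than 2 tags that rose and 2 that fell are printed. For the same reason the 36 gene lists fixed by product or symbol before the data were examined could not be matched, except for the pGKT2 genes. The xpl genes, the plasmid's known genes for degradation of the explosive RDX, could not be told apart from other pGKT2 tags. Replicons were assigned from the tag series (chromosome ro00001 to ro07282, pRHL1 ro08001 to ro09150, pRHL2 ro10001 to ro10458, pRHL3 ro11001 to ro11334), which is background knowledge of the RHA1 numbering and not a column of the files. Replicons were tested as sets with camera (preset correlation 0.01), or with cameraPR on the moderated statistics where slide was a random block, which camera does not take. Means over 20 genes consecutive in tag order were set against 1000 shuffles of the gene order within replicons, two-sided, by the largest absolute mean of each shuffle. The rule for named genes, fixed before the data were examined, took the RHA1 genes past the threshold whose replicates did not overlap (at most 12 per direction) and the 8 pGKT2 genes with the smallest adjusted p, besides RDX degradation genes, members of gene lists and up to 4 genes of the best window. With tags alone, both RHA1 genes and the first of the 8 are printed.

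The file headers place the arrays on 2 slides, scanned separately. Slide 1 held all wild-type arrays and transconjugant 1, and slide 2 held transconjugants 2 and 3. Median processed intensity per array was 50.2 to 97.7 units over a median local background of 26 to 37 units, and 95.5% to 99.0% of gene spots were well above background. The number of arrays limits the precision. The median 95% interval of an RHA1 gene was ±0.26 on the log2 scale, or 1.20-fold. On simulated data for this comparison with 8822 genes and 200 changed, limma recovered 91 of 100 genes changed 2-fold (1 log2 unit) and 98 of 100 changed by 2 log2 units, with 4 false calls. The simulated noise took each gene's residual SD from the real fit, which includes the spread between slides and cultures within a strain. It was independent between genes and arrays, so no slide or culture pattern shared by genes was simulated. The 200 changed genes also make the adjusted threshold easier to pass than few would. Recovery on the real arrays may thus be lower. Alternatives covered leaving out each culture, the replicate number or the slide as a block, slide 1 alone, the background correction, the scaling, the authors' log2 table, the filter, the choice of probe, the variance model and a 2-fold minimum. The planned normexp correction used the median spot signal. Quantile normalization over RHA1 probes alone and a variance prior from RHA1 genes alone were added after seeing the data, as were the bounds of plasmid genes with normexp, the quantile fit that left out pGKT2 genes but not their ranks, and the estimated correlation in the slide fits.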

Results

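The series measured transcript levels in R. jostii RHA1 with and without pGKT2, a plasmid of Gordonia sp. KTR9 known to carry the xplA and xplB genes for degradation of the explosive RDX. Separate cultures, 3 of the wild type and 3 of the RHA1/pGKT2 transconjugant, were grown in LB and each hybridised to 1 single-colour array. The arrays carried 8972 RHA1 genes and 159 pGKT2 genes. Between 8801 and 8867 RHA1 genes were well above background per array, and the number of arrays limited the precision. The first comparison shows which plasmid genes gave a signal in the new host, and the second which of the host's own genes differed once it held the plasmid.

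All 159 pGKT2 genes were well above background on all 3 transconjugant arrays, against 11 to 14 of them per wild-type array. All 159 were higher in the transconjugant (limma, adjusted p under the threshold for each, none lower). The median pGKT2 signal, on the log2 scale relative to each array's 75th percentile, was 0.25, 0.61 and 0.57 in transconjugants 1, 2 and 3. In wild-type cultures 1, 2 and 3 it was -5.82, -6.42 and -5.72. The plasmid signal of each array thus matched its labelled strain.

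Most plasmid genes had only background in the wild type. Of the 159, 145 were not well above background on any wild-type array. Their signal in the transconjugant was at least 20.6-fold higher at the median, with bounds from 5.41-fold to 74.3-fold, and 134 of the 145 bounds exceeded 10-fold. With the normexp correction and its offset of 50, the same bounds, added after seeing the data, were lower, at least 3.11-fold at the median and from 1.39-fold to 8.60-fold. Within slide 1, where the transconjugant is 1 array, the median bound with the processed signal was at least 17.4-fold. KTR9_RS00430, 1 of 2 genes tied at the smallest adjusted p and the one with the smaller unadjusted p, had a log2 signal of 1.24 ± 0.09 (SD, n = 3) in the transconjugant and -5.97 ± 0.14 (SD, n = 3) in the wild type. Its signal was at least 35.0-fold higher with the processed signal (limma, adjusted p = 3.49e-11). With normexp the measured difference was 4.47-fold, and over the alternatives the adjusted p of limma ran from 1.18e-12 to 2.51e-07. The other plasmid genes had some wild-type signal. For 10 of them all 3 wild-type arrays were well above background, and the transconjugant was 1.87-fold to 22.1-fold higher, with a median of 2.81 log2 units. The wild type lacks pGKT2, so these folds compare probe signals and not expression of the plasmid genes in both strains. The source of the wild-type signal was not tested. A further 4 genes were well above background on only 1 or 2 wild-type arrays, and no fold is given for them.

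**Figure D1:**
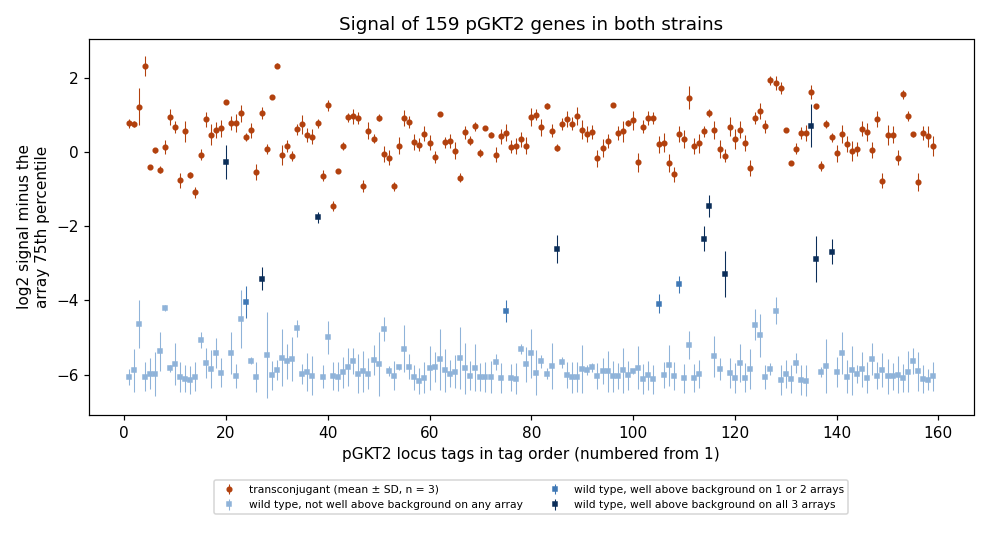
Signal of each of the 159 pGKT2 genes in tag order (x axis) as log2 signal minus the array's 75th percentile (y axis), as mean ± SD of 3 arrays per strain. Transconjugant means lie above the wild-type mean of the same gene for all 159 genes, and the 10 dark squares are genes with wild-type signal well above background on all 3 arrays.

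Of 8822 RHA1 genes tested, 1 rose and 1 fell in the transconjugant (limma, adjusted p under 0.05). The gene that rose, RHA1_ro05336 on the chromosome, had a log2 signal of 1.21 ± 0.54 (SD, n = 3) against -1.37 ± 0.13 in the wild type, a 5.97-fold difference (2.58 ± 0.23 SE, limma adjusted p = 0.0093). The gene that fell, RHA1_ro04919 on the chromosome, had 0.08 ± 0.44 (SD, n = 3) against 2.78 ± 0.34, a 6.49-fold difference (-2.70 ± 0.24 SE, limma adjusted p = 0.0093). For both genes the 3 values of one strain lay outside those of the other. Over all RHA1 genes, 13.5% had such non-overlapping values, where chance gives 10%. The middle 90% of RHA1 genes differed by -0.38 to 0.10 log2 units, and 15 differed by at least 2-fold whether or not they passed the test. If no gene differed, a share of 0.05 of the 8822 would be expected at an unadjusted p under 0.05. At that level, 49 genes were higher and 689 lower. This total of 738 ran from 372 without wild-type culture 3 to 2210 with slide as a fixed block, with 1925 without transconjugant 1 and 1601 within slide 1. The direction moved with the scaling. The main 75th percentile took in the pGKT2 probes, brighter on the transconjugant arrays, which lowered all RHA1 differences by the same amount. With the percentile over RHA1 probes alone, the median RHA1 difference went from -0.07 to 0.02 log2 units. At an unadjusted p under 0.05, 120 genes were then higher and 326 lower. The middle 90% ran from -0.29 to 0.18, and 3874 genes in place of 6717 lay below 0. Part of the excess of lower genes thus came from the scaling. The same 2 genes passed.

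**Figure D2:**
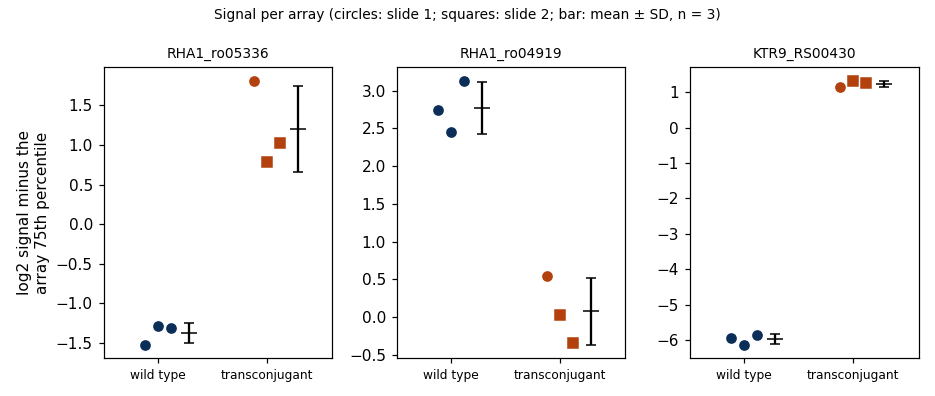
Log2 signal minus the array's 75th percentile for the RHA1 gene that rose, the RHA1 gene that fell and the pGKT2 gene KTR9_RS00430, with 1 point per array and mean ± SD beside each strain. No wild-type value overlaps a transconjugant value in any panel.

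The arrays of slide 2 bore on these counts. Within slide 1, transconjugant 1 against the 3 wild-type arrays gave 3.19 log2 units for RHA1_ro05336 (limma adjusted p = 0.00038) and -2.24 for RHA1_ro04919 (limma adjusted p = 0.11). These p-values rest on the spread of the wild-type arrays alone, and transconjugant 1 is assumed to vary like them. With slide as a fixed term the differences were the same, because slide 2 held no wild-type array. Counts and p-values of that fit thus also rest on 1 transconjugant array for the strain difference. Over all alternatives the adjusted p of limma ran from 0.00012 to 0.090 for RHA1_ro05336 and from 0.00017 to 0.11 for RHA1_ro04919. Without transconjugant 1, which shared the wild type's slide, 633 RHA1 genes passed, 16 higher and 617 lower. Without wild-type culture 1 no RHA1 gene passed in limma, although 514 had an unadjusted p under 0.05, and both named genes had an adjusted p of 0.082.

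The scaling of the arrays changed the number and the direction of the RHA1 calls. After quantile normalization over all probes, 11 RHA1 genes were higher and 328 lower, and the authors' deposited table, tested with the same limma fit, gave 12 higher and 321 lower. The 2 sets of lower genes shared 302 members. When RHA1 probes were quantile-normalized without the pGKT2 probes, a fit added after seeing the data, 6 genes were higher and 11 lower, and all 17 were among the genes called with all probes. Both named genes passed in each of these 3 fits. With each array's median in place of its 75th percentile no RHA1 gene passed in limma (564 at an unadjusted p under 0.05), and both named genes had an adjusted p of 0.090. The median difference of all RHA1 genes was -0.07 log2 units at the 75th percentile, -0.08 after quantile normalization over all probes and 0.02 over RHA1 probes, by quantile normalization or the 75th percentile.

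**Figure D3:**
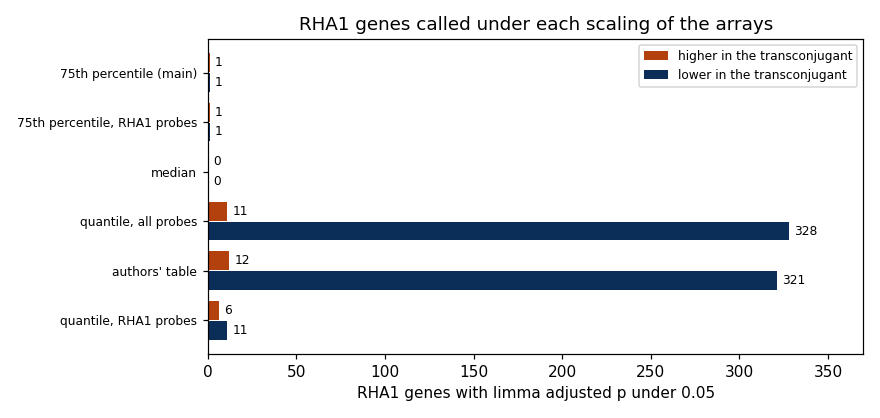
Number of RHA1 genes with limma adjusted p under 0.05 (x axis), higher or lower in the transconjugant, under 6 scalings of the arrays (y axis). Lower genes number 328 and 321 where pGKT2 probes entered a quantile normalization or the authors' table was used, and 11 after quantile normalization over RHA1 probes alone.

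The host's replicons were compared because the transconjugant carried a further plasmid beside the resident pRHL1, pRHL2 and pRHL3. Relative to the median of all RHA1 genes, the median gene of pRHL3 was 0.07 log2 units higher in the transconjugant (319 genes, camera adjusted p = 4.79e-09) and that of pRHL2 0.04 higher (407 genes, adjusted p = 7.78e-05). Neither call held with an estimated correlation between genes (adjusted p = 0.67 for pRHL3 and 0.69 for pRHL2 with an estimated correlation). The chromosomal median was -0.0077 (7138 genes, adjusted p = 0.0043, or 0.14 with an estimated correlation), and that of pRHL1 was 0.0042 (958 genes, adjusted p = 0.81). No gene of pRHL1, pRHL2 or pRHL3 passed limma on its own. At an unadjusted p under 0.05 there were 45, 18 and 12, or 4.70%, 4.42% and 3.76% of those tested, against 9.29% on the chromosome. The plasmid shares were no higher than the 0.05 expected if no gene differed. With 2 called genes, the planned comparison of the share of changed genes between replicons could show nothing. With slide as a fixed block or within slide 1, where the transconjugant is 1 array, the directions were opposite, at -0.03 for pRHL3, -0.08 for pRHL2 and 0.02 for the chromosome, and pRHL1 passed at -0.09 (camera adjusted p = 1.01e-06 with the block and 2.40e-06 within slide 1). With an estimated correlation these calls were lost (adjusted p = 0.51 to 0.68 for the 3 plasmids, and 0.13 for the chromosome within slide 1) except the chromosome's with the block (adjusted p = 0.032). With slide as a random block and the preset correlation pRHL1 passed at -0.06 (adjusted p = 2.08e-05) and pRHL3 no longer passed (0.0033, adjusted p = 0.67). Without transconjugant 2 the chromosomal median was 0.00066 and the pRHL2 call was lost at 0.0043, the chromosomal call was lost without transconjugant 3 or wild-type culture 3, and pRHL1 passed at 0.053 without transconjugant 1. The pRHL2 median also grew with the processing, to 0.10 with normexp, 0.13 after quantile normalization and 0.14 in the authors' deposited table.

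Along the RHA1 tags, means over 20 consecutive genes passed the level of the shuffled gene orders in 5 separate stretches, all on the chromosome and all lower in the transconjugant. That all were falls depended on the scaling: with the 75th percentile over RHA1 probes alone 5 falls and 2 rises passed, and with quantile normalization over them 3 falls and 2 rises. The largest lay at ro06132 to ro06151, with a mean difference of -0.50 log2 units, larger in size than any stretch of either sign in 1000 shuffles of the gene order (two-sided permutation p = 0.001, the smallest they can give). Measured against the wild-type mean, it was -0.66 and -0.83 in transconjugants 2 and 3 but -0.01 in transconjugant 1, the array on the wild type's slide, and -0.11, -0.09 and 0.20 in wild-type cultures 1, 2 and 3. The strains did not separate there (exact permutation p = 0.30, two-sided, where 3 against 3 cannot go below 0.10). With slide as a fixed or random block, with slide 1 alone, without transconjugant 3 or with quantile normalization over RHA1 probes, the largest fall lay elsewhere on the chromosome. After quantile normalization over all probes and in the authors' deposited table it lay on pRHL1 from ro08004 to ro08088. The size of the largest fall, wherever it lay, ran from -0.32 to -0.88 over the alternatives. Where the largest fall of 20 genes overlapped ro06132 to ro06151, it ran from -0.36 to -0.75. The largest means of the other 4 stretches ran from -0.34 to -0.45. At ro01796 to ro01817 the values were -0.28, -0.47 and -0.44 in transconjugants 1, 2 and 3 and -0.07, -0.05 and 0.12 in wild-type cultures 1, 2 and 3, and at ro06057 to ro06076 they were -0.25, -0.49 and -0.41 against -0.06, -0.04 and 0.10. At ro01407 to ro01426 they were -0.09, -0.40 and -0.52 against -0.07, -0.06 and 0.13. In these 3 stretches each transconjugant lay below each wild-type culture (exact permutation p = 0.10 each, two-sided, the smallest possible). At ro02850 to ro02869 transconjugant 1 did not, with -0.09, -0.60 and -0.64 against -0.16, -0.02 and 0.18 (exact permutation p = 0.20, two-sided). All 5 windows were picked for their strain difference on these same arrays, which favours separation of the strains. The largest rise, on pRHL2 at ro10154 to ro10173, had a mean of 0.29 and did not pass this test (two-sided permutation p = 0.21). Shuffled falls, down to -0.39, set that two-sided level, and no rise in the 1000 shuffles exceeded 0.17. Set against shuffled rises alone, which was not the planned test, the permutation p of the rise was 0.001. The rise was 0.45, 0.30 and 0.13 in transconjugants 1, 2 and 3. In wild-type cultures 1, 2 and 3 it was 0.13, -0.01 and -0.12 (exact permutation p = 0.20, two-sided). It passed the planned test at 0.45 with slide as a fixed block or slide 1 alone, at 0.40 with slide as a random block, at 0.37 without transconjugant 3, at 0.36 without wild-type culture 1, and at 0.37 with the 75th percentile over RHA1 probes. With quantile normalization over RHA1 probes, added after seeing the data, it passed at 0.41. No gene of the 20 in the largest window of any of the 5 stretches, or in the largest rise, passed limma on its own (44 of 100 and 7 of 20 at an unadjusted p under 0.05), and the shuffles compare gene orders, not cultures. Choosing windows by their strain difference also favours low unadjusted p among their genes.

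**Figure D4:**
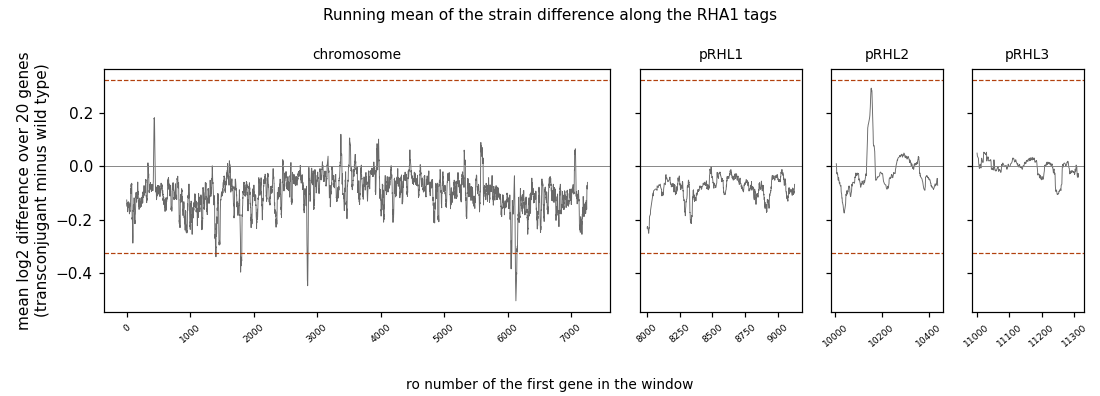
Mean log2 difference between transconjugant and wild type over 20 consecutive genes (y axis) by the tag number of the first gene (x axis), per RHA1 replicon. Dashed lines mark the two-sided level of 0.324 in either direction, which 5% of shuffled gene orders passed anywhere. The pRHL2 peak of 0.29 stays inside it, and the deepest chromosomal trough reaches -0.50. Shuffled falls set this level, and no shuffled rise exceeded 0.17.

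The 150 RHA1 genes that were not tested were unevenly placed. Of these, 99 lay among the 150 pRHL1 genes with tags ro08001 to ro08159. In that stretch 87 genes were well above background on no array of either strain, 13 on 1 to 5 arrays and 50 on all 6. Elsewhere 5 of 8822 RHA1 genes were well above background on no array, and none of these was among the other 913 pRHL1 genes (Fisher's exact test, inside against outside the stretch, p = 2.6e-161, with genes not independent of each other). The stretch was singled out after its values were seen and was ended at its last undetected gene. The lack of undetected genes just past it and the size of the Fisher p follow in part from that choice.

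**Figure D5:**
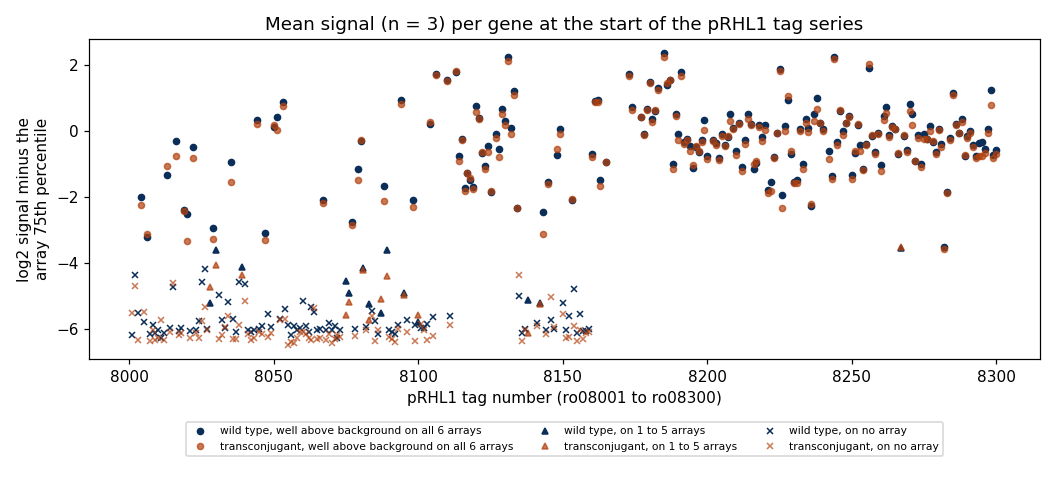
Mean log2 signal of 3 arrays per strain minus the array's 75th percentile (y axis) for genes at the start of the pRHL1 tag series (x axis, tag number), with the symbol giving the number of arrays well above background. Crosses are the 87 genes not well above background on any array of either strain, with a wild-type median of -5.96. The stretch was ended at the last cross, ro08159.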

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

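The count of RHA1 genes past the threshold, 2, moved to 1 with slide as a fixed block or slide 1 alone, 10 with trend and robust variance, 339 after quantile normalization, 333 with the authors' table, 0 with each array's median, and 17 with quantile normalization over RHA1 probes, chosen after seeing the data. Leaving out 1 culture gave 0 to 633: 633 without transconjugant 1, 0 without wild-type culture 1 and 2 otherwise. RHA1_ro05336 ranged from 1.58 to 3.19 over 21 alternatives (limma adjusted p 0.00012 to 0.090), past the threshold in 19, and RHA1_ro04919 from -2.93 to -2.12 (0.00017 to 0.11), past it in 17. All 159 pGKT2 genes were called in 18 of 20 alternatives; a 2-fold minimum left 158, and requiring detection on all 6 arrays left 10 to test, and all 10 were called. Relative replicon medians reversed with slide as a fixed block and with slide 1 alone (the same value in both), to 0.022 for the chromosome, -0.085 for pRHL1, -0.084 for pRHL2 and -0.028 for pRHL3, and with slide as a random block to 0.014 for the chromosome, -0.058 for pRHL1 and -0.050 for pRHL2, where pRHL3 no longer passed at 0.0033. Leaving out 1 culture gave -0.024 to 0.00066 for the chromosome, -0.022 to 0.053 for pRHL1, 0.0043 to 0.11 for pRHL2 and 0.052 to 0.14 for pRHL3. The pRHL2 median was 0.10 with normexp, 0.13 after quantile normalization, 0.11 over RHA1 probes and 0.14 with the authors' table, and the chromosomal one -0.016, -0.012 and -0.016 in the last 3. With an estimated correlation the medians, -0.0077, 0.040 and 0.074 for the chromosome, pRHL2 and pRHL3, no longer passed. The largest fall among means of consecutive genes passed in all 23 alternatives, windows of 10 and 40 genes among them. Its ends lay at different places. It was -0.32 at ro01796 to ro01817 after quantile normalization over RHA1 probes, and -0.88 at ro08004 to ro08088 on pRHL1 after that over all probes. The largest fall overlapped the stretch of the main fit in only 14 of the 21 alternatives with 20-gene windows. The largest rise, not past the threshold at 0.29, passed at 0.45 with slide as a fixed block or slide 1 alone, 0.40 with slide as a random block, 0.37 with the 75th percentile over RHA1 probes and 0.41 with quantile normalization over them, and leaving out 1 culture gave 0.22 to 0.37 (past it without transconjugant 3 or wild-type culture 1); it overlapped its stretch in 20 of 21. With the replicate block the RHA1 count was 2 and no call changed. Deviations of same-numbered cultures correlated at -0.39, 0.32 and -0.59, and not every culture correlated best with its own number. The distance of transconjugant 1, alone of its strain on slide 1, and that of wild-type culture 3 shape all these correlations. They thus neither show nor exclude pairing. Where causes are not given in the other observations, the cause was not tested. The planned gene list tests were not run because no list could be matched to tags. Signal over background, 50.2 to 97.7 units against 26 to 37, limits what dim genes can show.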

Other observations

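The tests of the pRHL1 stretch and of hybridisation or scanning of slide 2 were chosen only after the result was seen. So were the quantile normalization over RHA1 probes alone, whose prediction was written before its result, and the fit that left out pGKT2 genes but kept their ranks. Predictions on spot noise and on the cultures of slide 2 were written before their results.

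The first pattern is the set of pRHL1 tags without signal in both strains. At ro08001 to ro08159 the 87 undetected genes had a median log2 signal of -5.96 on the wild-type arrays and -6.16 on the transconjugant arrays, and the 50 genes detected on all 6 arrays had a median of -0.70 in the wild type. Probes failing without regard to place would be scattered, yet up to 19 of 20 consecutive tags were undetected, where 1000 shuffles of the gene order reached at most 5. The stretch was not continuously silent: detected genes lay among the undetected ones along the tags, with up to 21 in a row detected on all 6 arrays. Whether part of the segment was missing from the cultures of both strains or its genes were present but scarcely transcribed cannot be told apart without DNA of the cultures. The undetected genes differed by -0.0368 log2 units at the median from the 145 pGKT2 genes that no wild-type array detected, but both sets were chosen for lack of detection and lie at the arrays' floor under either explanation, and the 0.0567% of RHA1 genes undetected elsewhere does not decide it either.

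The second pattern is the excess of lower RHA1 genes after quantile normalization. Of the 328 lower genes called over all probes, 3.35% were called again when RHA1 probes were normalized alone, and their median difference went from -1.32 to -0.10 log2 units (interquartile range -0.30 to 0.02) at nearly the same standard error (median 0.11 and 0.10), while leaving pGKT2 genes out of the fit but not out of the ranks kept all 328. This is consistent with the pGKT2 probes, bright on one strain's arrays and dim on the other's, taking ranks from RHA1 genes and lowering them in the transconjugant, and the authors' table, whose lower calls shared 302 genes with that fit, may carry the same shift. Whether the remaining differences reflect the strain or only the cultures and slide of transconjugants 2 and 3 stays open. Genes called lower from those 2 cultures against 2 wild-type cultures were lower in transconjugant 1 than in the third wild-type culture by -5.58, 1.11 and 39.9 percentage points more often than other RHA1 genes, with wild-type culture 2, 1 or 3 as the third.

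The third pattern is the distance between transconjugant 1 and the other transconjugants, where 348 RHA1 genes passed for slide in the fit with a slide term, within the transconjugant (limma adjusted p under 0.05), 82 higher and 266 lower on slide 2. This sets 1 array against 2 with the spread taken mostly from the wild-type arrays, so it describes these arrays and does not count genes that differ between slides or culture conditions. Noise of spots or of their place on the array is argued against by the correlation of the difference over all RHA1 genes between neighbours in tag order, which was 0.448 after its trend with signal level was removed (largest of 1000 shuffles 0.035). For place this holds only if neighbours in tag order lie at unrelated places on the array, which was assumed. The arrays did not group by strain. Transconjugant 1 correlated at 0.959 and 0.965 with transconjugants 2 and 3, but at 0.975, 0.979 and 0.985 with wild-type cultures 1, 2 and 3, which shared its slide. Hybridisation or scanning of slide 2 stays open: across RHA1 genes the difference correlated at 0.592, level trend removed, with wild-type cultures 1 and 2 minus culture 3, all on slide 1, but this rests on culture 3 (the contrasts for cultures 1 and 2 gave -0.354 and -0.319, and culture 1 minus culture 2 gave 0.0445). Slopes of RHA1 signals against slide 1 were 0.885 and 0.886 on slide 2 and 0.945 to 1.04 among the arrays of slide 1, while those of the spike-in probes were 1.033 and 1.003 against 0.994 to 1.005, and a difference between the cultures, for which the 348 genes decide nothing, cannot be told apart from the slide because slide 2 held no wild-type array.

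With 3 arrays per strain there are 10 splits, too few for a share under 0.05. The real split called 2 RHA1 genes and was the only 1 with any (highest other 0). It called 159 pGKT2 genes (1 split as large, highest other 0). Each other split mixed the strains within both groups, so the lack of pGKT2 calls there was fixed in advance. RHA1 genes shared their fit and its variance prior with those mixed pGKT2 values, so the RHA1 counts of the other splits decide little. For the replicon sets, 7 of the 10 splits called at least as many as the real split, which called 3 (highest other 4).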
